A study of Mus musculus with 4 samples.

How the data were processed

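Gene expression was measured in immortalized mouse fibroblasts on Illumina bead arrays, with 4 libraries in 4 groups and 1 library per group. Per the labels, a library came from cells given a control miRNA, miR-141, miR-200c or none of these. The title of the last library names the transfectant, while its transfection field says none. It was read here as cells given the transfection reagent only and is called transfectant only. The transfection lasted 48 h, and all 4 cultures received 400 µM hydrogen peroxide for the last 2 h before lysis. Total RNA was extracted, its quality was checked on a Bioanalyser and it was turned into biotinylated cRNA, per the labels' protocols. The labels do not say which arm of each miRNA precursor was transfected.

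The deposited table of non-normalized values held an average bead signal intensity per probe and array on a linear scale, per the file headers, with no scaling between arrays. Beside each signal the deposited table gave a detection p-value, which set the probe against the background of its own array. GenomeStudio was named in the submitters' processing notes, and its version and settings were not given in the sources used here. A second deposited table held the authors' processed intensity values, whose method was not stated. Set against the raw signals, each column of it was a straight line of that array's own signals, to within 0.0113 intensity units, so the scale was linear and the genes were not centred. The slopes were 0.692 for transfectant only, 1.51 for control miRNA, 1.00 for miR-141 and 0.971 for miR-200c, with intercepts of 12.1, -19.9, -0.90 and 3.94. The medians of the processed columns were 46.3, 44.7, 45.0 and 45.8 in the same order. How the authors chose these lines was not given in the sources used here. The number of value columns without a library was 0.

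Raw signals were background-corrected with normexp from the detection p-values, quantile-normalized and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). All 4 arrays were normalized together. Later steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Quantile normalization gives every array the same distribution of values, so a shift shared by most genes would be removed. Background correction and the offset set how large the difference of a dim probe comes out.

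Probes were named from the platform annotation. Of 46632 probes, 29976 had a single gene symbol, 10 had several and 16646 had none. Through Entrez identifiers, 29921 probes were found in a RefSeq gene table of assembly GRCm38.p6, and 0 were renamed. No coordinates were used. For each of 17711 genes the probe with the highest mean over the 4 arrays was taken. A probe counted as detected in a library at a detection p-value under 0.01, which left 7734 genes detected in at least 1 library and 6485 in all 4.

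With 1 library per group, no test between groups could be run and no p-value is given. Genes were called by a fixed size instead. A gene was higher or lower with a miRNA when it was detected with that miRNA or in both control libraries, and its log2 difference was at least 0.585 (1.5-fold) in the same direction against both control miRNA and transfectant only. The reported difference is the one against control miRNA unless stated otherwise. The control libraries were compared with each other at the same 1.5-fold size, and the miRNA libraries with each other among genes that passed the rule with at least 1 of them. In each trio of a miRNA and both controls, genes were also counted in which a single library stood 1.5-fold apart from the other two.

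A gene below detection in a library has only a bound there. Its fold is given as "at least", from the brighter normalized value against the higher of the dim probe's own value and the lowest detected signal of that array. For a comparison with both controls, the smaller of the 2 folds is given. The lowest detected log2 signals were 5.29 for transfectant only, 5.33 for control miRNA, 5.36 for miR-141 and 5.37 for miR-200c.

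For 26 gene lists fixed before the data were examined, the median log2 difference of the members detected in at least 1 library was set among the medians of 10000 random lists of the same size. The random lists were matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Lists with fewer than 3 detected members have no percentile. The lists of published targets were written from memory of the literature, not from a database. A further 2 lists, used only among the closing observations, were written after the leading genes had been seen.

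The genes named in the text were set by a rule fixed in advance. It took the 12 higher and 12 lower genes per miRNA with the largest smaller-of-both differences, the 8 largest each way between the miRNAs and the 6 largest each way between the controls. It also took up to 4 passing members per list, always Zeb1, Zeb2, Mapk14, Keap1, Cdh1, Vim and Fn1, and list members as examples of values. Of the 115 genes named by the ranked parts of the rule and the passing list members, 30 had another detected probe. Of the 41 such probes, 34 had the same direction as the named probe with miR-141 and 33 with miR-200c. Histone genes have near-identical copies, so probes can share signal among copies and their values are uncertain.

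Agreement between the miRNAs was measured as Pearson's r, Spearman's rho and covariance across 7734 genes, which are not independent replicates. Because a shared control library alone gives a positive correlation, the value with no effect was simulated 100 times, and the agreement was also computed with a different control for each miRNA. The simulation gave every library independent noise of equal size, so its r values follow from that setting.

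The calling rule was tested on simulated data for the comparison with miR-141, with 200 of 7734 genes shifted by a known fold. It recovered 33% of genes shifted 1.5-fold, 80.5% of those shifted 2-fold and 100% of those shifted 4-fold. With no gene shifted, the simulation called 72 genes higher and 87 lower. Its noise was set from the spread of control miRNA minus transfectant only and was equal for every library.

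The alternatives tried were no background correction, scaling to a common median, the authors' processed values, an offset of 50, other detection filters, the mean of a gene's detected probes, thresholds of 1.3-fold and 2-fold, and other choices of control. Comparisons of genes with and without seed matches to either miRNA had been planned. They needed 3' UTR sequences, which were not used here, and were left out.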

Results

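The data comprised 4 expression arrays of immortalized mouse fibroblasts under acute oxidative stress, 1 array for each transfection. Fibroblasts are connective tissue cells that normally make little miR-141 or miR-200c, related miRNAs of the miR-200 family whose seed regions differ at a single base. The controls were cells given transfectant only and cells given a control miRNA. All cultures received hydrogen peroxide, so the effect of the peroxide itself was not compared. The median raw signal was 49.5 for transfectant only, 42.8 for control miRNA, 45.8 for miR-141 and 43.1 for miR-200c, and the mean was 246, 151, 198 and 190. Of 46632 probes, 11747, 11519, 11381 and 11339 were detected in the same order, which gave 7152, 7119, 7033 and 6989 detected genes. None of the differences below has a replicate check, since each group had a single library, and the number of arrays limits the precision.

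The first comparison asked which transcripts differed in cells given miR-141. Zeb1 and Zeb2, repressors of epithelial genes and established targets of the miR-200 family, were lower with miR-141 by log2 differences of -1.14 and -1.28 against control miRNA and of -1.41 and -1.31 against transfectant only. Mapk14, which encodes the stress kinase p38 alpha, was 1.88-fold lower than in control miRNA and 2.20-fold lower than in transfectant only. Transcripts typical of epithelium stood out at the other end, with the laminin chain gene Lamb3 at least 6.14-fold higher and the tight junction gene Cldn4 at least 2.16-fold higher than in the controls. In all, 170 genes were higher and 226 lower with miR-141 against both controls, among 7188 genes considered. Of the higher genes 38 were below detection in both controls, and of the lower genes 42 were below detection with miR-141. With undetected values at their bound 354 genes passed, against 396. For scale, the simulation without any change called 72 higher and 87 lower among 7734 genes, all treated as detected. Its noise came from the difference between the controls and was equal for every library. The measured controls were not equal in this way. In the same trio control miRNA stood apart in 74 genes and transfectant only in 214, so the simulated count is no firm level without effect.

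The genes with the largest differences in the upward direction with miR-141 also included Syne4, which encodes the outer nuclear membrane protein nesprin-4 (at least 4.44-fold), and Ckmt1, a mitochondrial creatine kinase (at least 3.53-fold). Lmntd2 was at least 2.11-fold higher, the Snail-family gene Snai3 at least 1.95-fold, the keratin gene Krt8 at least 1.81-fold and the cytokine gene Il24 at least 1.60-fold. These 6 genes were below detection in both controls. Genes measured in all 4 libraries were Ctsw, a cathepsin, at a log2 difference of 2.09, Tmem130 at 1.69, Stxbp2, a regulator of vesicle fusion, at 1.67, and Tprn at 1.61. At the lower end stood Ppt2, a lysosomal thioesterase, at -2.75, the glucuronosyltransferase gene Ugt1a7c at -2.05 and Fcgrt, the neonatal Fc receptor chain, at -1.82. Next came the secreted matrix protein gene Spon2 at -1.77, Ccn5 at -1.65, Chid1 at -1.63 and Dmwd at -1.62. Of 2 other detected probes of Chid1, only 1 had the same direction. Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, was at -1.54, the heme oxygenase gene Hmox1 at -1.47 and the non-coding Snhg18 at -1.46. The retinaldehyde dehydrogenase gene Aldh1a3 was at least 2.73-fold lower and Olfml3 at least 1.74-fold lower, both below detection with miR-141.

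Among 16 detected genes listed as published targets of miR-141 and miR-200a, 5 were lower and 0 higher with miR-141. These were Zeb1, Zeb2, Mapk14, Tgfb2 at -0.79 and Clock at -0.64, while Keap1, the adaptor that marks NRF2 for degradation, was at -0.00 against control miRNA and 0.16 against transfectant only. The median of this list was -0.27, at percentile 0.08 of the matched random lists. Collagens and other matrix genes had a median of -0.34 over 23 genes, below every random list (percentile 0), although control miRNA was itself lower than transfectant only by a median of -0.17 (percentile 1.1), with the crosslinking enzyme gene Loxl2 at -1.17, the collagen chaperone gene Serpinh1 at -0.74, Col6a2 at -0.74 and Col5a1 at -0.69 among 4 lower and 0 higher. Mesenchymal factors and markers had a median of -0.26 over 13 genes (percentile 0.25), with 5 lower and 0 higher. Besides Zeb1 and Zeb2 these were S100a4 at -0.93, Twist2 at -0.61 and the growth factor receptor gene Pdgfrb, at least 2.27-fold lower, while Vim at -0.08 and Fn1 at -0.05 did not pass. Of the epithelial markers, only 5 of 22 on the array were detected in any library, and 4 of these 5 were higher with miR-141, among them Krt7 (at least 1.70-fold) and Spint1 (at least 1.31-fold). Their median was 1.20, or 0.77 with undetected values at their bound. Cdh1, the E-cadherin gene, was below detection in all 4 libraries.

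Without background correction 198 genes passed the rule for miR-141, and with the authors' processed values 192 did. The epithelial median was then 0.63 and 0.60, and over all 22 markers on the array, with the 17 undetected ones included, it was 0.084. Of the 5 detected markers only Krt19 was detected in the controls, so the others entered the list through the miRNA libraries, and for this reason no percentile is given.

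The second comparison put the same question to miR-200c. The lowest transcripts included several published targets of this miRNA, each measured in all 4 libraries. Crtap, part of the complex that hydroxylates collagen prolines, was 6.29-fold lower than in control miRNA. The phosphatase gene Ppm1f was 5.94-fold lower, Zeb1 4.86-fold, the VEGF receptor gene Flt1 4.54-fold, the vesicle coat gene Sec23a 4.01-fold and the formin gene Fhod1 3.94-fold. Keratin genes below detection in both controls were bright with miR-200c, with Krt8 at least 5.66-fold and Krt7 at least 5.57-fold higher. With miR-200c 293 genes were higher and 328 lower against both controls, among 7202 genes considered. Of the higher genes 82 were below detection in both controls, and of the lower genes 67 were below detection with miR-200c. With undetected values at their bound 537 genes passed, against 621.

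Of the genes with the largest differences in the upward direction with miR-200c, Lamb3 was at least 8.38-fold higher, Syne4 at least 7.65-fold, the chemokine gene Cxcl16 at least 4.79-fold and Cldn4 at least 4.51-fold. The microtubule-associated protein gene Map7 was at least 4.08-fold higher, Ckmt1 at least 4.05-fold and Il24 at least 3.45-fold. Llgl2, a cell polarity gene, and Kng1, which encodes kininogen, were both detected in all libraries and both stood at a log2 difference of 2.73, with Psca at 2.21. At the lower end, Spon2 was at -3.26, the glutamate receptor subunit gene Gria1 at -1.92, the endocytic adaptor gene Dab2 at -1.91, the transcription factor gene Tbx3 at -1.89, and Vasn, whose product binds TGF-beta, at -1.88. The immediate early gene Egr3 was at -1.97. Fkbp7, a prolyl isomerase of the endoplasmic reticulum, was at least 2.49-fold lower and Rtl3 at least 2.34-fold lower, both below detection with miR-200c.

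Published targets of miR-200b, miR-200c and miR-429 had 10 lower and 1 higher among 19 detected genes with miR-200c. The lower ones were Crtap, Ppm1f, Zeb1, Flt1, Sec23a, Fhod1, Zeb2 at -1.40, the actin-binding Msn at -1.05, Ptpn12 (at least 1.42-fold) and Cfl2 (at least 1.22-fold), and the higher one was Tubb3, which was below detection in control miRNA. The list median was -0.94 (percentile 0), or -0.51 with undetected values at their bound. Matrix genes had 9 lower and 1 higher of 23, with a median of -0.48 (percentile 0). Lower were Col6a1 at -1.21, Col6a2 at -1.12, Col1a1 at -1.09, Lox, which crosslinks collagen, at -1.08, Col5a1 at -1.06, Timp1 at -0.93, Mmp2 at -0.76, Bgn at -0.71 and Tnc at -0.59, and the proteoglycan gene Dcn was higher at 2.15. Mesenchymal factors and markers had 6 lower and 0 higher of 13 and a median of -0.47 (percentile 0.01), with Pdgfrb at least 2.25-fold lower, S100a4 at -1.36, Prrx1 at -0.76 and Tcf4 at -0.73. Vim at -0.32 and Fn1 at -0.33 did not pass. All 5 detected epithelial markers were higher, including Krt19 at 1.64 and Spint1 (at least 3.14-fold), with a median of 2.70 or 2.17 with bounds. The other 17 on the array, Cdh1 among them, were below detection in every library. Actin and adhesion genes had 7 lower and 2 higher of 25. Besides Ppm1f, Fhod1, Msn and Cfl2, the lower ones were Acta2 at -0.93, Tln1 at -0.96 and Rhob at -0.60, and the higher ones were Ezr at 1.10 and Itgav at 0.69. The median of this list was -0.09 against control miRNA (percentile 10.6) and -0.35 against transfectant only (percentile 0).

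Without background correction 363 genes passed the rule for miR-200c, and with the authors' processed values 350 did. The median of the published miR-200c targets was then -0.47 and -0.45, and that of the epithelial markers 1.68 and 1.64, or 0.13 over all 22 on the array.

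**Figure D1:**
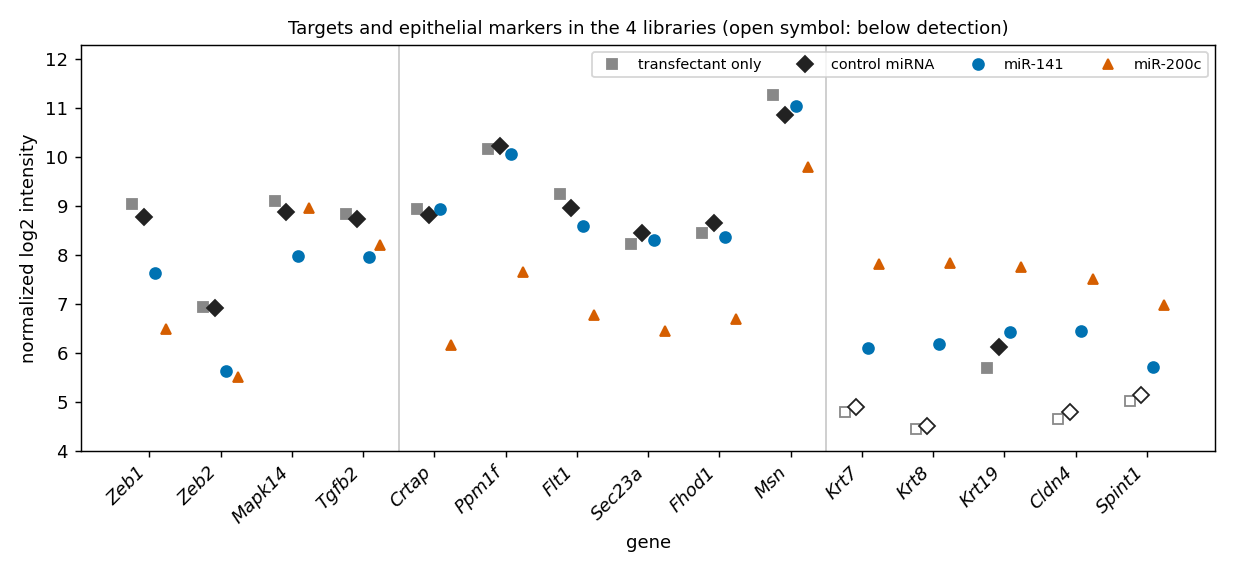
Normalized log2 intensity (y axis) of published targets and epithelial markers (x axis) in the 4 libraries, 1 symbol per library, with open symbols where the probe was below detection. Zeb1 and Zeb2 were below both controls with either miRNA, Mapk14 with miR-141, and Crtap and Ppm1f with miR-200c, while Krt7, Krt8, Cldn4 and Spint1 were detected only with the miRNAs.

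The third comparison set the miRNAs against each other. Of the published miR-200c targets, Crtap was 6.86-fold lower with miR-200c than with miR-141, Ppm1f 5.31-fold, Sec23a 3.64-fold, Flt1 3.52-fold and Fhod1 3.22-fold. The list of these targets was higher with miR-141 by a median of 0.41 (percentile 100), or 0.20 with undetected values at their bound. In the opposite direction, Ppt2 was 6.07-fold lower with miR-141 than with miR-200c, and Mapk14 1.98-fold lower, but the published miR-141 targets as a list differed by a median of -0.03 for miR-141 minus miR-200c (percentile 34.5), or 0.01 with undetected values at their bound. Zeb2 differed little between the miRNAs, at a log2 difference of 0.12 for miR-141 minus miR-200c, while Zeb1 was at 1.15. The epithelial markers were lower with miR-141 than with miR-200c by a median of -1.33 over the 5 detected ones. Of these only Krt19 was detected in the controls, so the others entered through the miRNA libraries compared here. The value does not describe the markers that were below detection in every library.

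Among genes that passed the rule with at least 1 miRNA, 157 were higher with miR-141 and 183 were higher with miR-200c by 1.5-fold. Further genes higher with miR-141 were Depdc1b and the growth factor gene Ptn, both at 1.80, and Gria1 at 1.66. Further genes higher with miR-200c were Dmwd at -1.91 for miR-141 minus miR-200c, the TGF-beta co-receptor gene Tgfbr3 at -1.83, the kinase gene Map3k3 at -1.82, Kng1 at -1.81, the linker histone gene H1f2 at -1.78, Cdk19 at -1.77 and the fatty acid receptor gene Ffar4 at -1.74. Without background correction 171 genes differed between the miRNAs, and with the authors' processed values 174 did. The larger share turned to miR-141 with the authors' values (91 against 83) and with detection in all 4 libraries (133 against 120).

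The same direction was nonetheless common. With both miRNAs against both controls, 94 genes were higher, where independent lists of these sizes would share 7.10, and 108 were lower, where they would share 10.6. Higher with both were, for example, Lamb3, Syne4, Ckmt1, Krt8 and Cldn4, and lower with both were Spon2, Zeb1, Zeb2, Fcgrt and Ugt1a7c. Opposite directions were found for 1 gene higher with miR-141 and 2 genes lower with it. The higher one was Depdc1b, at 0.63 with miR-141 and -1.17 with miR-200c. The lower ones were Map3k3, at -1.23 with miR-141 and 0.59 with miR-200c, and the aldehyde dehydrogenase gene Aldh3a1, named after its values were seen, at -0.92 and 0.78. Part of the excess of shared genes may come from the shared controls, and with a different control for each miRNA 135 or 136 genes were higher with both, where independence gives 21.8 or 28.5, and 149 or 170 were lower, where it gives 32.6 or 39.9. Across 7734 genes, the differences correlated with r = 0.65 and rho = 0.61 when both were taken against control miRNA, where simulated libraries without any effect gave r = 0.50. The covariance was 0.107 against 0.0562 without effect. With both taken against transfectant only, r was 0.71 and rho 0.69. With different controls, r was 0.40 and 0.36, rho 0.31 and 0.23, and covariance 0.0713 and 0.0680, where the simulated r was -0.002.

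**Figure D2:**
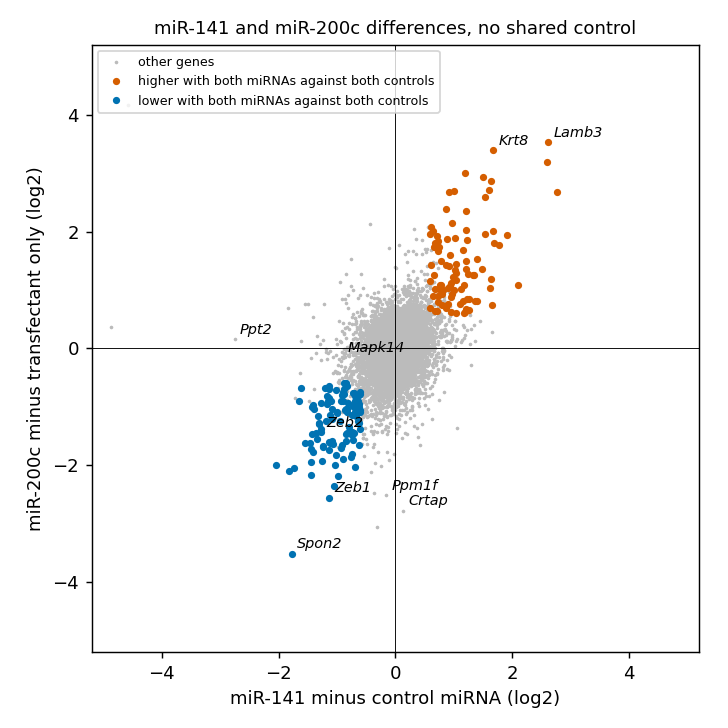
Log2 difference of each detected gene with miR-141 against control miRNA (x axis) and with miR-200c against transfectant only (y axis), so that no control library is shared. Coloured points are the 94 genes higher and the 108 lower with both miRNAs against both controls, and over all points r was 0.40.

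The controls were compared with each other to give the size of differences between libraries without either miRNA. Fbxw5, part of a ubiquitin ligase, was at least 18.2-fold higher in control miRNA than in transfectant only and was below detection in the other three libraries. Pop4, an RNase P subunit gene, was at least 20.2-fold higher in control miRNA than in transfectant only, and at least 14.6-fold higher with miR-200c than with miR-141. Whether these values come from a fault of the probe or the array could not be checked with 1 array per group. Apart from these, the largest differences in the upward direction were the H2A histone genes H2ac19 at 1.47 and H2ac18 at 1.27, whose near-identical copies make them uncertain, the iron exporter gene Slc40a1 at 1.47 and Tenm4 at 1.46. Lower in control miRNA were the amino acid transporter gene Slc7a2 (at least 2.15-fold), the protease gene Adamts5 (at least 1.63-fold), Psmd6 (at least 1.29-fold), Kctd12 at -1.29, Igfbp5 at -1.21 and Wnt5a at -1.20.

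By the 1.5-fold size, 237 genes were higher and 339 lower in control miRNA than in transfectant only, among 7509 genes considered. This 41.2% share of higher genes was 59.9% with median scaling and 63.4% with the authors' processed values, so no direction is read from it. The count was 128 without background correction. In the trio of miR-141 and both controls, miR-141 stood apart from the other two in 396 genes, control miRNA in 74 and transfectant only in 214. In the trio with miR-200c the counts were 621, 97 and 209. Over the 6485 genes detected in all 4 libraries, the standard deviation of the log2 difference was 0.30 between the controls, 0.34 and 0.40 for miR-141 and miR-200c against control miRNA, and 0.40 and 0.45 against transfectant only. Between the controls it was 0.40 among the dimmest 2578 detected genes, 0.33 among the middle 2578 and 0.26 among the brightest 2578.

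The remaining lists covered stress responses, proliferation and other cell types. NRF2 and antioxidant genes had medians of -0.08 with miR-141 (percentile 8.22) and -0.12 with miR-200c (percentile 6.02) over 20 genes, and of -0.08 and -0.10 against transfectant only. Only Hmox1 passed with miR-141. With miR-200c, where Hmox1 was at -0.57, Tkt of the pentose phosphate pathway was higher at 0.92 and Blvrb, at least 1.09-fold, was lower. Genes of the p38 pathway had medians of 0.02 (percentile 60.6) and 0.25 (percentile 99.6) over 18 genes, and of -0.09 and -0.01 against transfectant only, with Mapk14 lower with miR-141 and the kinase gene Mknk1 lower with miR-200c at -1.04. Of 23 immediate early genes, 4 were lower and 0 higher with miR-141, and 4 lower and 1 higher with miR-200c, with list medians of -0.07 (percentile 14.0) and -0.11 (percentile 10.04). Against transfectant only these medians were -0.05 (percentile 21.3) and -0.20 (percentile 1.62). Egr2 was at -0.70 and -1.33, Egr3 at -1.06 and -1.97, and Dusp2 at least 1.24-fold and 1.23-fold lower with miR-141 and miR-200c. Klf4 was lower with miR-141 at -0.61, Dusp5 was lower with miR-200c at -0.72, and Atf3 was higher with miR-200c at 0.98.

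Among 16 inflammatory genes, with medians of 0.01 (percentile 55.2) and 0.15 (percentile 93.5), or 0.10 and 0.19 against transfectant only, the NF-kB inhibitor gene Tnfaip3 was higher with both miRNAs at 1.65 and 1.14, and the chemokine gene Cxcl12 lower at -1.44 and -0.85. Lcn2 was at least 1.07-fold and 1.25-fold higher. Ccl7 was lower with miR-141 at -0.72. With miR-200c Cxcl1 was higher at 1.85, Icam1 at least 1.27-fold higher, and Vcam1 lower at -0.87. Genes of the endoplasmic reticulum stress and amino acid response had medians of -0.13 (percentile 3.11) and -0.15 (percentile 4.26) over 22 genes. Against transfectant only they were -0.35 (percentile 0) and -0.34 (percentile 0.06), or -0.20 and -0.28 with undetected values at their bound. Lower with both miRNAs were Xbp1 at -0.83 and -0.79, Chac1 at -0.92 and -0.93 and Vldlr at -0.79 and -1.04. Atf5 was lower with miR-141 at -0.59 and Ppp1r15a higher with miR-200c at 1.02. TGF-beta pathway genes had medians of 0.01 and 0.02 over 21 genes (percentiles 49.96 and 58.9), and of -0.15 and -0.17 against transfectant only (percentiles 5.01 and 3.78). Tgfb1 was lower with both at -0.91 and -0.83, Tgfbr3 with miR-141 at -1.29, Tgfb2 with miR-141, and Acvr1 with miR-200c at -0.62, while Tgfbr2 at 0.82 and Bmp4 at 0.80 were higher with miR-200c.

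Genes of G2/M and mitosis had medians of 0.26 with miR-141 (percentile 99.98) and 0.23 with miR-200c (percentile 99.58) over 18 genes, but 0.10 and 0.08 against transfectant only, and a single member passed, Ccnf with miR-200c (at least 1.20-fold). S phase genes had medians of -0.02 and 0.08 over 22 genes (percentiles 31.0 and 86.8), or -0.04 and 0.06 against transfectant only, with Mcm7 lower with miR-141 at -0.78 and Ccne2 at least 1.26-fold higher with miR-200c. For p53 targets the medians were -0.03 and 0.01 over 15 genes (percentiles 35.9 and 53.5), with Plk2 at 0.74 and Fas at -0.75 with miR-141 and the cell cycle inhibitor gene Cdkn1a at 0.95 with miR-200c. The control libraries differed for this list by a median of 0.25 (percentile 98.94), and against transfectant only its medians were 0.10 (percentile 76.8) and 0.27 (percentile 98.1). Cholesterol synthesis genes had medians of 0.17 (percentile 98.73) and -0.09 (percentile 15.1) over 16 genes, and of -0.08 (percentile 16.4) and -0.34 (percentile 0.1) against transfectant only, and Mvk was lower with miR-200c at -0.68. The controls also differed for cholesterol synthesis genes, by -0.16 (percentile 1.92), for TGF-beta pathway genes, by -0.15 (percentile 2.49), and for ribosomal protein genes, by 0.21 (percentile 99.95). No member passed with either miRNA among 11 heat shock genes (medians 0.02 and -0.01), 20 glycolysis and hypoxia genes (0.05 and 0.12), 17 ribosomal protein genes (-0.09 and -0.12), 22 oxidative phosphorylation genes (-0.06 and -0.02) or 9 reference genes (0.11 and 0.02). Against transfectant only these medians were -0.16 and -0.11 for heat shock genes, -0.04 and 0.17 for glycolysis and hypoxia genes, 0.07 and -0.04 for ribosomal protein genes, -0.06 and 0.00 for oxidative phosphorylation genes and -0.10 and -0.08 for reference genes. With median scaling the reference gene medians were -0.15 and -0.14 against control miRNA.

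Interferon response genes had 5 detected members, medians of 0.09 and 0.10, or 0.21 and 0.15 against transfectant only, and Bst2 at least 1.35-fold lower with miR-141. Markers of other cell types gave 4 detected endothelial genes with medians of -0.09 and 0.17, or -0.03 and 0.11 against transfectant only, of which none passed. The medians of 3 muscle genes were -0.16 and -0.14 against control miRNA but 0.46 (percentile 97.0) and 0.80 (percentile 99.5) against transfectant only, and of these Acta1 was higher with miR-200c at 0.70. Of 2 detected leukocyte markers Cd14 was higher with both miRNAs at 0.59 and 0.79, and of 2 adipocyte markers none passed. The medians of these pairs were 0.32 and 0.17 for leukocyte markers and -0.08 and -0.04 for adipocyte markers, or 0.29 and 0.14, and -0.18 and -0.13, against transfectant only. For the published miR-141 targets the median with miR-200c was -0.01 (percentile 49.7) against control miRNA but -0.31 (percentile 0.37) against transfectant only. Lower among them were Zeb1, Zeb2 and Egfr, at -0.71, although the 1 other detected probe of Egfr did not share this direction. For the published miR-200c targets the median with miR-141 was -0.26 (percentile 0.14), or -0.18 (percentile 3.22) against transfectant only, with Zeb1 and Zeb2 lower.

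**Figure D3:**
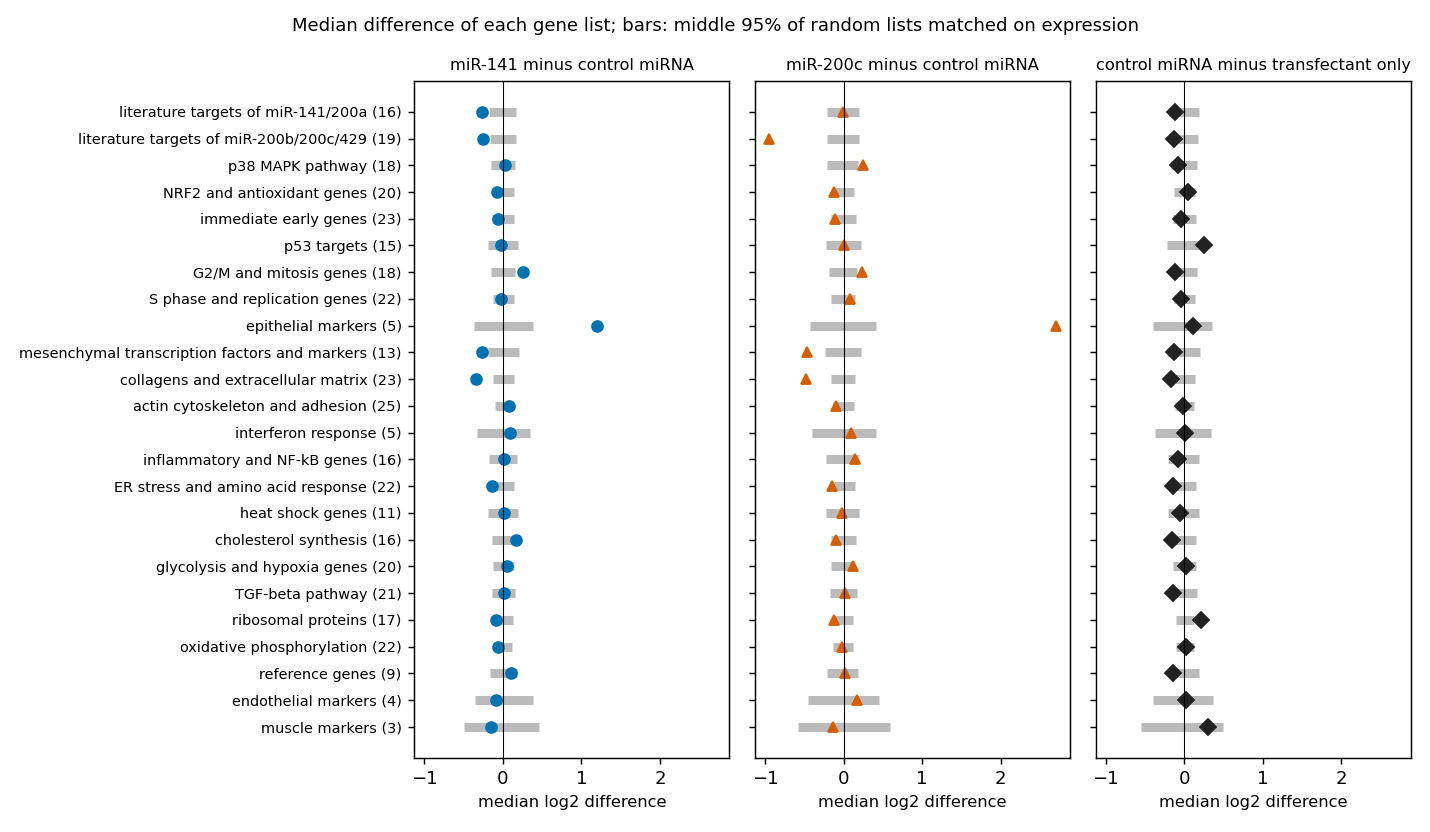
Median log2 difference (x axis) of each gene list (rows, with the number of detected genes), with miR-141 and with miR-200c against control miRNA and for control miRNA against transfectant only. Grey bars span the middle 95% of 10000 random lists matched on expression. The epithelial markers, of which only the 5 detected ones entered, stood at 1.20 and 2.70 with the miRNAs and at 0.11 between the controls. All but 1 of these entered through the miRNA libraries, so their distance from the bars carries no weight. Over all 22 markers on the array the medians with the miRNAs were 0.084 and 0.13.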

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

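The probes described here lie outside the comparisons of named genes and were counted after those comparisons had been seen. Of 16656 probes without a gene name or with several, 118 stood 1.5-fold apart from both controls in the same direction with miR-141, while control miRNA stood apart in 29 and transfectant only in 83. With miR-200c 210 such probes stood apart, against 58 for control miRNA and 76 for transfectant only.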

How the results depend on the processing

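The counts against a single control and with undetected values at their bound were chosen after seeing the data; all other alternatives were set before. No leading median or correlation and no named gene that had passed the rule turned direction under any alternative run. The majority of higher or lower genes turned between the controls (237 against 339, but 377 against 252 with median scaling and 109 against 63 with the authors' values). It also turned between the miRNAs (157 against 183, but 91 against 83 with the authors' values, 133 against 120 with detection in all 4 libraries and 419 against 408 at 1.3-fold). Some other list medians changed sign, such as the reference genes. The epithelial and muscle lists gave no value with detection in all 4 libraries. Of 144 values for 16 leading results 73 stayed within the limits set (1.5 times for a count, the spread of random lists for a median, the gap between both correlations for a correlation) and 71 moved. Of 1316 values for single genes 1075 stayed and 241 moved, and of 358 values for other lists 275 stayed and 83 moved. The cause was not tested, except that a stricter filter, another threshold or 1 control in place of 2 changes by construction which genes can pass. Some settings also gave smaller log2 differences against the same 1.5-fold threshold. The standard deviation of miR-141 minus control miRNA was 0.34 in the main setting and 0.27 without background correction. It was 0.28 both with an offset of 50 and with the authors' values. No paired analysis was possible because each group had 1 library. Of the libraries only the controls could be left out in turn. The planned seed-match results and their alternatives (8mer sites only, 7mer-A1 sites added, sites for a single seed, shortest 3' UTR) were not run. Between 24.3% and 25.2% of the probes were detected on each array, and values near background limit the dim genes most.

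The counts are given for miR-141, miR-200c, control miRNA against transfectant only, miR-141 against miR-200c, and transfectant only standing apart in the trios with miR-141 and miR-200c. They were 198, 363, 128, 171, 46 and 56 without background correction. They were 192, 350, 172, 174, 57 and 48 with the authors' processed values, and 217, 383, 152, 182, 55 and 64 with an offset of 50. At 1.3-fold they were 939, 1242, 1844, 827, 888 and 796, so that transfectant only stood apart in nearly as many genes as miR-141. At 2-fold they were 105, 195, 40, 76, 15 and 19. Against control miRNA alone 676 genes passed with miR-141 and 1024 with miR-200c, and against transfectant only alone 1020 and 1225. With detection in all 4 libraries 337 genes differed between the controls, and transfectant only stood apart in 136 in the trio with miR-141. Of the genes higher and lower with miR-141, 86 of 170 and 106 of 226 kept their call with the authors' processed values, and with miR-200c 147 of 293 and 197 of 328, with 0 turned.

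The correlation of the miRNA differences with different controls was 0.356 and 0.318 without the detection filter, and 0.324 with the authors' processed values for miR-141 against transfectant only.

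Medians with miR-141 moved as follows. For published miR-141 targets they were -0.11 without the detection filter, -0.48 against transfectant only and -0.37 against the mean of both controls. Epithelial markers were at 0.63 without background correction, 0.60 with the authors' values, 0.68 with an offset of 50 and 0.084 without the detection filter, which lets in the 17 markers that were not detected. Mesenchymal genes were at -0.11 without the detection filter, -0.40 with detection in all 4 libraries, -0.15 with the mean of detected probes and -0.53 against transfectant only. Matrix genes were at -0.24 without background correction, with an offset of 50 and without the detection filter, -0.25 with the mean of detected probes and -0.50 against transfectant only.

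With miR-200c, published miR-200c targets were at -0.47 without background correction, -0.45 with the authors' values, -0.50 with an offset of 50, -0.23 without the detection filter, -1.23 with detection in all 4 libraries and -0.58 with the mean of detected probes. Epithelial markers were at 1.68, 1.64 and 1.80 without background correction, with the authors' values and with an offset of 50 and at 0.13 without the detection filter. Mesenchymal genes were at -0.62 with median scaling, -0.65 with the authors' values, -0.32 without the detection filter, -0.60 with detection in all 4 libraries and -0.59 against transfectant only. Matrix genes were at -0.64 against transfectant only.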

Other observations

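The tests of explanations in this part were chosen after the results they bear on had been seen, while the scalings and the detection filter that some of them use were set before. H2B histone genes parted the libraries in a way that did not follow the miRNAs. In 12 genes control miRNA and miR-200c were both at least 1.5-fold above transfectant only and miR-141, against 2 genes in the opposite direction. They were named after their values were seen and were H2bc4, H2bc7, H2bc9, H2bc11, H2bc13, H2bc15, H2bc22, H2ac19, H1f2, Pop4, Cdkn1a and Ampd2, and whether Pop4 reflects a fault of its probe or array could not be checked. H2bc11, for example, had log2 values of 7.96 in control miRNA and 7.91 with miR-200c, but 6.76 in transfectant only and 7.01 with miR-141. The division of controls from miRNAs held 204 genes, and the remaining division of the 4 libraries into pairs held 8.

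For 8 of 9 detected H2B genes both libraries of the first pair were above both of the second, under each of 5 scalings, with a median difference between the pairs of 0.86 on the log2 scale, or 0.69 with the authors' values. The same held for 6 of 8 H4 genes, 2 or 3 of 12 H2A genes and 0 of 5 H3 genes. The H4 medians against control miRNA, however, were -0.37 with miR-141 and -0.38 with miR-200c, where the H2B medians were -0.81 and -0.05. The H2B genes named above had to stand above in this way by the rule that picked them, and the 5 scalings used the same arrays. The H2B count and median thus describe the pattern and are no separate support for it. In raw signals, before any scaling, the H2B median of miR-200c minus miR-141 was 0.68, where other genes as bright had -0.02. As these arrays were about equally bright in those other genes, a dimmer array does not account for the difference. The raw value is no separate test, since it had to repeat the difference by which the H2B genes were picked. For the controls, the raw H2B median of control miRNA minus transfectant only was -0.14, where other genes as bright had -0.93. The H2B signal thus fell less than theirs, but the H2B median was higher in control miRNA only after scaling. Whether dimmer arrays play a part here stays open, since the H2B genes were picked from these same arrays. More cells in S phase stay open, since the S phase list had a median of 0.027 with 9 members higher and 6 lower by more than 0.05. Signal shared among near-identical histone copies and other biological explanations were not tested.

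Epithelial genes were higher with both miRNAs, more so with miR-200c. Under each of 5 scalings, without a detection filter, at least 3 of all 22 list members with miR-141 were 1.5-fold above both controls. With miR-200c at least 5 were. The middle 95% of random lists matched on the controls reached at most 1 and 2, although with miR-141 the highest of 10000 lists also reached 3 with median scaling. The direction was thus kept under these scalings, but the size was not. With the authors' values the median of the detected markers fell from 2.70 to 1.64 with miR-200c and from 1.20 to 0.60 with miR-141. These members had already been seen to be higher on the same arrays, so the counts are no separate support. Epithelial cells mixed into the cultures stay open: only 5 of 22 members were detected with miR-200c, but undetected probes exclude nothing, as those of the fibroblast collagens Col1a2 and Col3a1 were undetected in all 4 libraries too. Release of these genes from Zeb1 and Zeb2 is a candidate explanation, as Zeb1 was at -2.28 with miR-200c and -1.14 with miR-141 and the epithelial medians were ordered likewise, while Zeb2 was at -1.40 and -1.28. With 1 library per miRNA it cannot be told apart from their other effects.

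Single genes of the endoplasmic reticulum, some of them acting on collagen, were among the lowest, namely Crtap and Fkbp7 with miR-200c and Kdelr3 with miR-141, although Crtap was at 0.12 with miR-141. Whether they stand for a group was asked of a list of collagen-modifying enzymes without these genes, of which 3 of 19 were lower with each miRNA and 0 higher. Its 18 members outside the matrix list lay below the middle 95% of matched random lists in 2 of 4 comparisons of a miRNA with a control. Their medians against control miRNA were -0.29 with miR-141 (percentile 0.04) and -0.20 with miR-200c (percentile 1.65), and against transfectant only the percentiles were 7.10 and 9.70. A list of genes for transport from the endoplasmic reticulum to the Golgi lay below in 1 of 4, against transfectant only with miR-141 (median -0.21). Neither list decides the question.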
